A study of Mus musculus with 6 samples.

How the data were processed

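RNA-seq was measured in 6 libraries of the tumoroid line, 3 of sorted GFP-high and 3 of sorted GFP-negative cells. Per the labels' protocols, total RNA was extracted with a column kit and made into strand-specific libraries. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.6, STAR 2.7.5b, Salmon 1.2.1 and DESeq2 1.30.1 and the builds mm10 and GRCm38, without their roles, order or options. The deposited estimated counts cover 54348 genes, and per the file headers each column is 1 library and each row 1 gene, with a versioned gene identifier and a symbol. The estimated counts are not whole numbers for 14.5% to 17.9% of genes per library, and they were rounded before any test. The authors also deposited normalized values, a signal on the count scale: each equals the rounded count divided by 1 factor per library, from 0.745 (GFP-high 3) to 1.68 (GFP-negative 1), within 0.1% for all genes with at least 1000 counts. Those factors were proportional to relative log expression factors computed from the counts, with ratios of 0.998 to 1.00. The annotation release is not given in the sources used here. Of the identifiers, 53309 matched the GENCODE release M21 list for GRCm38 with their version, and coordinates come from that release. No row of the table carried the name of a fluorescent protein, so the reporter's own transcript was not analysed here.

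Genes were tested with R 4.3.3 and edgeR 4.0.16, using TMM normalization, the filterByExpr filter by group and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment over the 14219 genes tested and a threshold of 0.05. The model held the group only. Fold changes are GFP-high over GFP-negative, the standard error is the one implied by the F statistic, and CPM uses TMM-scaled library sizes. Library totals of 14483619 to 31708120 counts set the precision: a gene with 0 counts in a whole group could have had up to 0.0465 CPM in GFP-high or 0.0410 CPM in GFP-negative cells (3 counts over the group), a limit that covers counting error only. Pairs of libraries of 1 group differed by 23.3 to 32.0 times the sampling variance (chi-square per degree of freedom over genes with at least 20 counts), so no 2 libraries were counted as 1.

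Both groups use the numbers 1, 3 and 4, and the labels do not say what a number marks. Deviations from the group means correlated between same-numbered libraries at 0.14, 0.16 and 0.14, each over the limit of 0.1 used for pairing, and at -0.14 to -0.00065 between libraries with other numbers. All 6 libraries correlated best with the library of their own number. These matches are not independent, because the deviations within a group sum to 0 for each gene. Of the 6 ways to match the libraries across the groups, the labelled one gave the highest sum of correlations, which chance gives in 1 of 6 cases. The pairing therefore comes from the data, and a fit with the replicate number as a block is given beside results where it changes a call or a count. The block's calls had been seen together with these correlations, and the decision followed the fixed limit.

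Before the data were examined, 33 lists of pathway and cell type genes, the tests and the rule for naming genes were fixed. The 31 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, with adjustment over the lists. The rule takes the 10 highest and 10 lowest fold changes and the 5 smallest p per direction among genes past the threshold with mean CPM of at least 5, non-overlapping groups and a symbol that is not a bare gene model or clone name (Gm with digits, Rik, LOC, ENSMUSG, AC, AL or CT) or a pseudogene symbol ending in -ps with or without a number; a fixed set of marker genes and the 4 engineered genes; and per list up to 4 members past the threshold with mean CPM of at least 1, or otherwise the 2 with the highest mean CPM, of which the text names only some. The same rule was applied to the blocked fit after its values were seen. Alternatives were relative log expression factors, no composition factor, other filters, DESeq2 1.42.0, limma-voom, limma on the deposited normalized values, a fold change limit and leaving out each library.

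The tests were tried on simulated counts with the real means, library sizes and dispersions, in which 200 genes were changed. For this comparison the fit without a block, on independent simulated libraries and 13840 genes, called 23.8% of genes changed 1.5-fold, 58.5% of those changed 2-fold and 76.9% of those changed 4-fold, with 6 false calls. On simulated pairs, over 13863 genes, the blocked fit called 45.3%, 71.2% and 83.1% with 15 false calls, and the fit without a block 1.56%, 47.0% and 76.9% with 0. A simulated list of 30 genes raised 1.25-fold gave a camera p of 3.2e-12 (0.0014 with an estimated correlation), and an unchanged list of 29 genes 0.50. The simulated genes varied independently of one another, whereas the fetal and regenerative list had an estimated correlation of 0.22. The simulation therefore does not test camera on lists whose members vary together.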

Results

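RNA was sequenced from 6 samples of 1 mouse intestinal epithelial tumoroid line. Tumoroids are tumour cells grown as small three-dimensional structures in culture. The line, named VAKPS_OnF in the labels and VAKSP in their titles, carries knockouts of Apc, Smad4 and Trp53 and the Kras G12D allele. Its labelled genotype also names a Cre recombinase driven by the Villin promoter, which is active in intestinal epithelium. The genotype entry does not say how each change was made. The line also stably carries a reporter of an oncofetal state, read out as green fluorescence (GFP). Selected tumoroids were expanded, and cells with high GFP and cells without GFP were collected by fluorescence-activated sorting, in 3 samples each, numbered 1, 3 and 4 in both groups. The series set out to test the reporter, so the comparison asked which genes differ between GFP-high and GFP-negative cells, and in particular whether genes of fetal and regenerating intestinal epithelium do. Totals ran from 14483619 estimated counts in GFP-high 3 to 31708120 in GFP-negative 1. GFP-high 1 held 26046945 estimated counts, GFP-high 4 held 23960574, GFP-negative 3 held 23204009 and GFP-negative 4 held 18146759. Mitochondrial transcripts took 2.34% to 3.90% of the counts, with the highest shares in GFP-high 3 and in GFP-negative 3 (3.59%). The labels do not say whether the samples of a group came from separate cultures or sorts, so the p-values measure the spread between these samples, which may be technical.

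Sorted GFP-high cells held more transcript of the coagulation initiator tissue factor (F3), the calcium-activated chloride channel Ano1, the prostaglandin synthase Ptgs1 and the cell surface glycoprotein mesothelin (Msln), and less of the vacuolar ATPase subunit Atp6v0e2, the adhesion protein teneurin Tenm3 and the T-box transcription factor Tbx3. F3 (chromosome 3, 121723537 to 121735048 in GRCm38) stood at 73.9 ± 5.18 CPM (counts scaled to a common library total; SD, n = 3) in GFP-high and 36.0 ± 2.12 in GFP-negative cells, a log2 fold change of 1.04 (SE 0.12, edgeR adjusted p = 0.0240). Ptgs1 stood at 80.2 ± 22.9 CPM against 25.2 ± 3.96 CPM, which is 3.18-fold higher. Ano1 was 3.14-fold higher, Cwh43, a factor in remodelling of membrane protein anchors, 2.98-fold, the bone morphogenetic protein family member Bmp3 2.89-fold, and the transmembrane protein Plxdc2 7.41-fold. Msln was 1.86-fold higher, at 41.4 ± 0.824 CPM against 22.2 ± 0.570 CPM (edgeR adjusted p = 0.0384). On the other side, Atp6v0e2 (chromosome 6, 48537615 to 48541801) stood at 6.56 ± 0.395 CPM in GFP-high and 27.5 ± 4.73 CPM in GFP-negative cells, 4.17-fold lower in GFP-high cells with a log2 fold change of -2.06 (SE 0.20, edgeR adjusted p = 0.0144). Armh4 was 7.14-fold lower, Tenm3 3.95-fold lower and Tbx3 1.74-fold lower. Tmem254c was 2.08-fold lower, but it is 1 of several near-identical neighbouring copies, and its counts are uncertain for that reason.

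These genes belong to a set of 15 that passed the threshold among 14219 tested, 9 higher and 6 lower in GFP-high cells. The groups did not overlap for any of the 15, so each gene necessarily went one way in all 3 pairs of libraries with the same number. Another 3 of the 15 fell outside the rule for naming genes and are named here after their values were seen. The fibroblast growth factor family gene Fgf14 had 79, 72 and 86 counts in the GFP-high libraries, 3 counts in GFP-negative 1 and 0 in the other 2 libraries. P3h2, a collagen-modifying enzyme, stood at 0.776 CPM against 8.70 CPM. Rps12-ps3, named as a copy of the ribosomal protein gene Rps12, had 383, 467 and 247 counts in GFP-high libraries and 0 in each GFP-negative library, at least 466-fold higher against a floor of 3 counts over the group. Reads shared with Rps12 make its level uncertain. The count of 15 depended on single libraries: without GFP-high 1, GFP-high 4 or GFP-negative 4 in turn edgeR called 0 genes (876, 1385 and 1185 at unadjusted p under 0.05), and without GFP-high 3 or GFP-negative 3 it called 4 and 5.

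**Figure D1:**
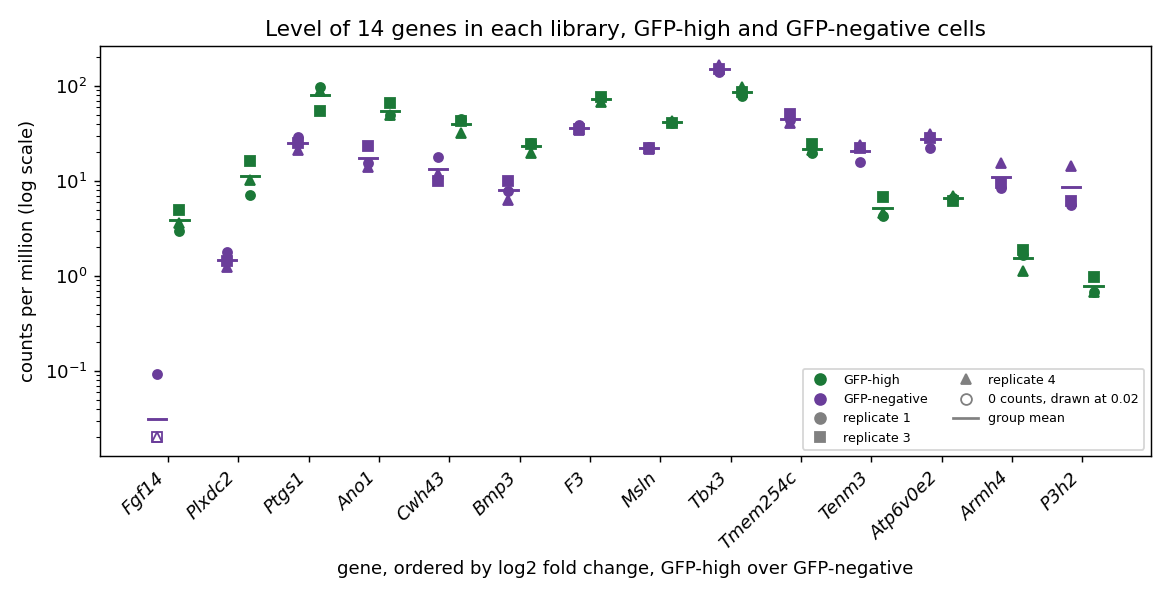
CPM (log axis) of 14 of the 15 genes past the threshold in each of the 6 libraries; Rps12-ps3, at 0 in all GFP-negative libraries, is left out. Green marks are GFP-high and purple marks GFP-negative libraries, the shape gives the replicate number, the bar is the mean of 3 libraries, and open marks are values of 0 drawn at 0.02. For every gene the groups do not overlap, as for Msln with group means of 41.4 and 22.2 CPM.

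With the replicate number as a block, Casd1, St8sia6, Krt14, Tff1, Cftr and Reg4 were among the genes that passed as higher in GFP-high cells, and Igfbp5, Fermt2 and Lcn2 among those that passed as lower. The block raised the count of changed genes to 184, with 81 higher and 103 lower, and the 15 genes above were all among them. The groups of 152 of the 184 did not overlap. Over all tested genes the groups did not overlap for 13.3%, where chance gives 10%. Among the genes added, the basal keratin Krt14 was 2.85-fold higher in the blocked fit (116.6 against 40.3 CPM, edgeR adjusted p = 0.0129 with the block and 0.0564 without it). The blocked fold was 15.0 for the sialic acid acetyltransferase Casd1 and 9.49 for the sialyltransferase St8sia6, 5.26 for the chloride channel Cftr, 4.97 for the gastric mucosal peptide Tff1, 4.77 for Medag, 3.35 for Dock11, 3.22 for the epithelial protein sciellin (Scel), 3.15 for the long non-coding RNA Lncenc1 and 3.07 for the secreted lectin Reg4. Sprr2a2 was 2.57-fold higher, but its counts are uncertain because near-identical Sprr2a copies lie beside it. The genes with the largest falls included the insulin-like growth factor binding protein Igfbp5, with a blocked log2 fold change of -2.93 (SE 0.38), Fam13c (-2.64), Susd4 (-2.48), the metalloreductase Steap4 (-2.38), the glycosyltransferase Galnt10 (-2.16), the integrin activator Fermt2 (-1.93) and the surface receptor Sirpa (-1.89). The iron-binding protein lipocalin (Lcn2) stood at 133.2 ± 20.7 CPM in GFP-high and 245.0 ± 57.4 CPM in GFP-negative cells (blocked log2 fold change -0.86, adjusted p = 0.00237 with edgeR). The ketone body enzyme Hmgcs2 had a blocked log2 fold change of -1.15.

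The list of fetal and regenerative epithelium genes, fixed before the data were examined, stood higher in GFP-high cells: 26 of its 35 tested members had a positive log2 fold change, with a median of 0.22 (camera adjusted p = 5.7e-06). This call was lost with an estimated correlation between genes (adjusted p = 0.53). Without the block 1 member, Msln, rose, 0 fell and 34 did not pass, and 4 rose when adjusted over the list alone. With the block 4 rose and 1 fell. Ly6a, which encodes the surface protein Sca-1 of regenerating crypts, stood at 1555 ± 246.8 CPM in GFP-high and 974.6 ± 324.5 CPM in GFP-negative cells, a log2 fold change of 0.67 (SE 0.20, edgeR adjusted p = 0.343), and passed with the block (log2 fold change 0.71, SE 0.09, adjusted p = 0.00500). The annexin Anxa3 was 1.84-fold higher with the block (134.7 against 73.5 CPM, edgeR adjusted p = 0.00271). Mfge8, which encodes a secreted glycoprotein, fell with the block (log2 fold change -0.70). Tacstd2, the surface antigen also known as Trop2, stood at 105.9 ± 33.6 against 76.3 ± 22.7 CPM (log2 fold change 0.47, SE 0.25) and did not pass in either fit. Anxa1, a gene at 516.8 against 555.4 CPM, and Clu, at 4.53 against 3.20 CPM, did not pass either, and Anxa10 had 0 counts in all 6 libraries. The median of the list differed between the pairs, at 0.03 in pair 1, 0.13 in pair 3 and 0.55 in pair 4.

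Wnt target and crypt base stem cell genes did not pass as a list (camera adjusted p = 0.65), with 12 of 30 tested members above 0. The list's median was -0.07, its mean 0.09, and camera's direction was down. None of its members passed without the block (edgeR 0 of 30, also 0 when adjusted over the list alone), and with the block 0 rose and 2 fell, the Wnt inhibitor Wif1 (log2 fold change -0.51, SE 0.08) and the secreted matrix protein Smoc2 (-0.43, SE 0.08). The crypt base receptor Lgr5 stood at 126.7 ± 44.5 CPM in GFP-high and 106.9 ± 29.3 CPM in GFP-negative cells (log2 fold change 0.24, SE 0.26), and neither Ascl2 (0.19) nor Axin2 (-0.03) passed. Olfm4 had 0 counts in all 6 libraries. For YAP/TEAD targets the camera adjusted p was 0.25, and 16 of 30 members were above 0. Members moved in both directions: F3 and Msln rose, the matricellular thrombospondin Thbs1 fell by 1.10 on the log2 scale with the block and Ccn1, a matricellular protein, fell by 0.57 with the block, while Ccn2 (0.49, SE 0.19) and Ankrd1, at 1.28 CPM in GFP-high cells, did not pass. Adjusted over the list alone, 4 YAP/TEAD targets rose and 2 fell.

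Cell cycle genes stood higher in GFP-high cells and cholesterol synthesis genes lower, both by small amounts spread over nearly the whole list. Of 39 cell cycle genes, 36 had a positive log2 fold change, with a median of 0.21 (camera adjusted p = 1.9e-10). With an estimated correlation the adjusted p was 0.26. No single cell cycle gene passed without the block (edgeR 0 of 39, and 4 when adjusted over the list alone), and with the block the mitotic genes Ube2c (log2 fold change 0.46, SE 0.08), Cenpf (0.53, SE 0.10) and Cenpe (0.48, SE 0.09) rose. The proliferation marker Mki67 stood at 223.0 ± 15.8 CPM against 174.6 ± 16.6 CPM (log2 fold change 0.35, SE 0.10, edgeR adjusted p = 0.335). Of 25 cholesterol synthesis genes, 2 had a positive log2 fold change, and the median was -0.22 (camera adjusted p = 1.0e-07). That call was lost with an estimated correlation (adjusted p = 0.18). The early pathway enzyme Hmgcs1 was the only member that passed with the block (292.9 against 396.3 CPM, log2 fold change -0.43, SE 0.08). Without the block 0 of 25 passed, and 4 fell when adjusted over the list alone.

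Squamous and basal keratin genes, gastric and foregut genes, and ion transport genes of the colon also stood higher in GFP-high cells as lists. For squamous and basal keratins 17 of 22 members were above 0, with a median of 0.55 (camera adjusted p = 2.1e-05), and with an estimated correlation the adjusted p was 0.53. Krt14 and Krt6a (log2 fold change 0.75, SE 0.14) rose with the block. Sprr2a3 rose as well, but it belongs to a cluster of near-identical Sprr2a copies, so its counts are uncertain. Gastric and foregut genes had a median of 1.15 over the 8 members tested, of 20 in the list. The camera adjusted p was 0.0052, and 0.26 with an estimated correlation. The genes not tested include Pgc and Anxa10, at 0 counts, and Muc6, Tff2 and Muc5ac, with at most 7, 8 and 20 in any library. Tff1 was the only member that passed with the block. The stem cell transcription factor Sox2 had a log2 fold change of -0.82 (SE 0.35) and did not pass. Solute carrier and ion transport genes of the colon had a median of 0.23 over 16 members (camera adjusted p = 0.015, and an adjusted p of 0.26 with an estimated correlation), with Cftr and the carbonic anhydrase Car2 (log2 fold change 0.88, SE 0.18) higher in the blocked fit. The keratin call ended without GFP-high 4 (adjusted p = 0.064), and the gastric call without GFP-negative 1 (adjusted p = 0.051) or GFP-negative 4 (adjusted p = 0.054). Adjusted over the list alone without the block, 2 keratin, 3 gastric and 2 ion transport genes rose and 0 fell.

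**Figure D2:**
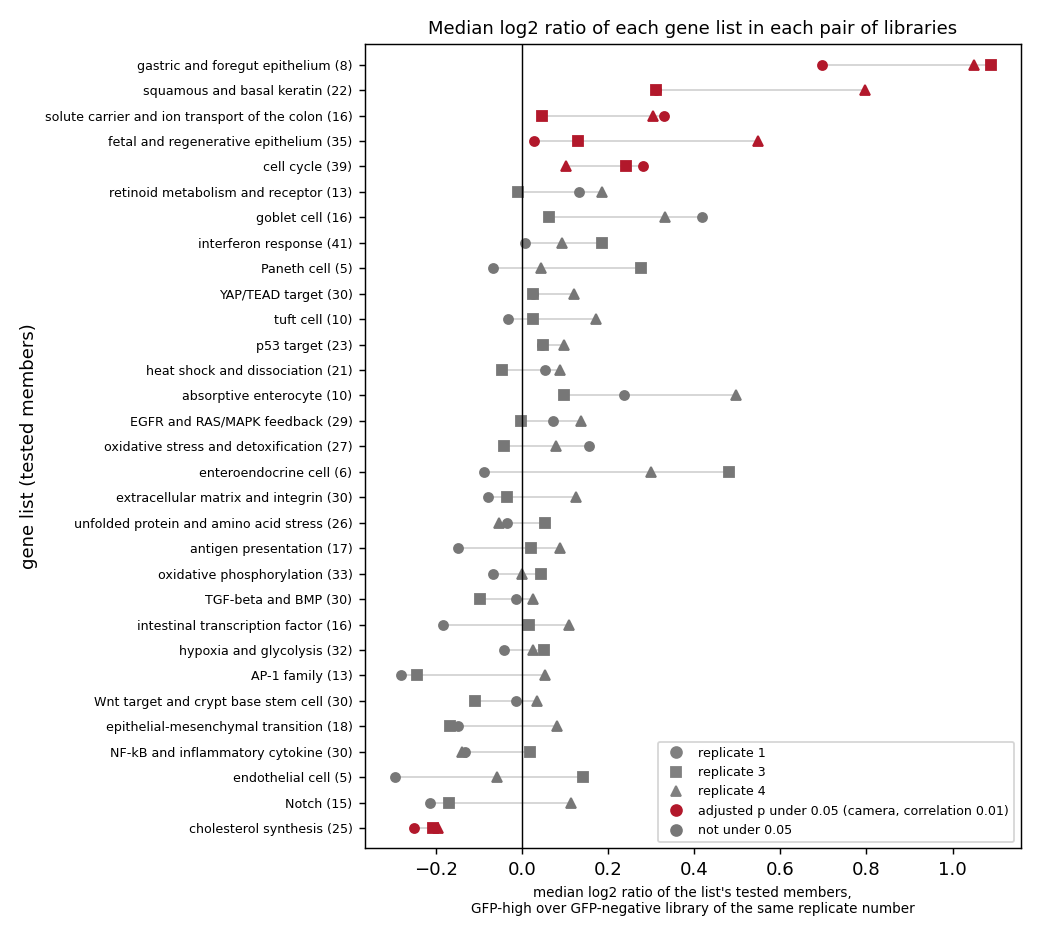
Median log2 ratio, GFP-high over GFP-negative, of the tested members of each of 31 gene lists, 1 mark per pair of libraries with the same replicate number; the number of tested members stands in brackets and red marks lists with a camera adjusted p under 0.05 at a preset correlation. The fetal list runs from 0.03 to 0.55 over the pairs, and the cholesterol synthesis list from -0.25 to -0.20.

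The other 25 lists did not pass, with camera adjusted p from 0.11 to 0.99. Among differentiated cell types, enteroendocrine genes (6 tested members) had an adjusted p of 0.20 and passed with the block (adjusted p = 0.0036), where Reg4 rose, but not with the block and an estimated correlation (adjusted p = 0.54). The tuft cell list had an adjusted p of 0.11, and Ptgs1 was its only member that rose; the list passed without GFP-high 3 (adjusted p = 0.0060) or GFP-negative 3 (adjusted p = 0.0052). Absorptive enterocyte (adjusted p = 0.55), goblet cell (0.16) and Paneth cell genes (0.65) did not pass, though the goblet cell list passed without GFP-negative 3 (adjusted p = 0.0099). Only 10 of 35 absorptive enterocyte, 16 of 24 goblet and 5 of 19 Paneth cell genes reached the level needed for a test. For enteroendocrine and tuft cells it was 6 of 28 and 10 of 22. Muc2, Lyz1, Alpi, Neurog3 and Pou2f3 had 0 counts in all libraries, so these lists test only part of each cell type's markers. The differentiation keratin Krt20 was at 2.10 CPM in GFP-high and 1.59 CPM in GFP-negative cells. AP-1 family genes (0.36, direction down, median -0.07, though Fosl1 had a log2 fold change of 0.52, SE 0.19), retinoid genes (0.25), with the receptor Rxra at a log2 fold change of -0.16, epithelial-mesenchymal transition genes (0.25), interferon response (0.26) and hypoxia and glycolysis genes (0.60) did not pass. Without 1 library, the hypoxia list passed without GFP-high 1 (adjusted p = 0.037). The heat shock and dissociation list (0.26 with all libraries, direction down) passed as lower without GFP-negative 4 (adjusted p = 0.0097). The interferon list passed in 4 of the 6 cases without 1 library, once in the other direction. The blocked fit gave further calls when a replicate number was left out. Without number 4 these were AP-1 family (adjusted p = 0.00025), epithelial-mesenchymal transition (adjusted p = 0.049) and heat shock and dissociation genes (adjusted p = 0.0041), all down. Without number 3 they were tuft cell (adjusted p = 0.00030) and oxidative stress genes (adjusted p = 0.012), and without number 1 interferon response (adjusted p = 0.0039). Vim and Lamb1 fell with the block, by 0.61 and 0.57 on the log2 scale, and Car9 (log2 fold change 0.88) and Ndrg1 (0.32) rose with it. H2-Q7 (-0.80) and Etv5 (-0.45), of the antigen presentation and EGFR lists, also fell with it. Of markers of other cell types, 1 of 16 fibroblast and 1 of 21 hematopoietic genes reached the level needed for a test, Fbln1 (log2 fold change -0.69) and Cd68 (0.15), and endothelial genes had an adjusted p of 0.90. Transcripts of the engineered genes did not differ between the groups beyond the spread: the log2 fold change was -0.01 for Apc (SE 0.22), 0.12 for Kras (SE 0.10), 0.27 for Smad4 (SE 0.20) and -0.32 for Trp53 (SE 0.19). Both groups share 1 genotype, and totals over a gene do not test a deletion of part of it.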

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

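The alternatives that leave out a replicate number in the blocked fit, remove a GC trend or combine the block with other list tests were chosen after the data were seen. The count of 15 changed genes kept within 1.5 times with relative log expression factors (15), no composition factor (14), a stricter filter (19), limma on the deposited normalized values (20 and 13 with pseudocounts of 1 and 0.1) and a fold change of at least 2 (13). It was 483 with no filter on low counts (26109 genes tested), 3 with limma-voom, 232 with DESeq2 and 449 with DESeq2 and the replicate block; the cause was not tested. All 15 genes were also called by DESeq2, and 130 of its 232 genes were among the 184 of the edgeR fit with the replicate block, as were 183 of the 449. Leaving out 1 library gave 0 to 13 genes, with fewer samples in each fit. Of the 15 calls, 15 were lost without GFP-high 1, GFP-high 4 or GFP-negative 4, 12 without GFP-high 3 or GFP-negative 3, and 7 without GFP-negative 1. The replicate block gave 184, and 231 with a GC trend removed, which kept 179 of the 184. Leaving out both libraries of number 1, 3 or 4 from the blocked fit gave 125, 417 and 190 genes, of which 97, 171 and 122 were among the 184.

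The number of lists past the threshold was 6, and 7 with the replicate block, 6 with relative log expression factors and 5 to 9 without 1 library. It was 10 in the blocked fit without number 4. It was 0 with an estimated correlation or fry (4 and 7 at unadjusted p under 0.05), and 0 in the blocked fit with an estimated correlation or fry (2 and 9 unadjusted). For the fetal and regenerative list the adjusted p was 0.53 with an estimated correlation, 0.46 with fry, and in the blocked fit 0.54 and 0.29; without 1 library camera gave 1.0e-10 to 0.035. The Wnt and YAP/TEAD lists stayed above the threshold in each alternative run for lists (relative log expression factors, the replicate block, estimated correlation, fry and the leave-outs). Without 1 library the interferon response list ran from 3.2e-05 to 0.97, and without GFP-negative 3 its direction turned to down (adjusted p = 0.030). The replicate block moved 43 of the named genes, many of them named because of it, past the threshold and no gene or list back across it; besides the enteroendocrine list it changed no other list's call.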

Other observations

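The tests of the immediate-early genes and of a copy number difference were chosen after the result was seen, and the predictions of the other tests were written down before their results were seen, though the patterns themselves had been noticed. Among the genes without a place in the lists, 7 had 0 counts in all libraries of one group and at least 10 counts in each library of the other. Besides Rps12-ps3, which was counted in GFP-high cells, these were counted in GFP-negative cells: Soga3 (51, 48 and 42 counts), the neuronal RNA-binding protein gene Elavl2 (40, 27 and 43), Mxra7, Sspn, Bend5 and the sulfotransferase gene Chst7. Lower depth of the group at 0 was argued against by the library totals. GFP-high 1 and GFP-high 4 (26046945 and 23960574 counts) were deeper than GFP-negative 3 and GFP-negative 4 (23204009 and 18146759 counts). Both had 0 counts of the 6 genes counted in GFP-negative cells. Rps12-ps3 had 0 counts in GFP-negative 1, the deepest library, and 467 in GFP-high 3, the shallowest. The smallest summed count that the other group's level predicts for a group at 0 was 45.9. The choice of genes alone sets it to at least 26.5, so this value by itself does not test depth. Of the 10 ways to split the 6 libraries into groups of 3, 2 gave as many such genes, and the highest of the others gave 8 against 7 for the real split, so 10 splits are too few to test chance here, and the count does not stand out among them.

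The real split gave 15 genes without a block and the highest of the other 9 splits gave 2 (1 of 10 splits gave as many). Of the 4 splits that part every pair, only the real one gave as many genes with the block (1 of 4), 184 against 0 in the others. Neither 10 nor 4 splits can give a share under 0.05. The lists behaved otherwise: 4 of the 10 splits gave 6 lists or more, and the highest other split gave 11. An adjusted p for the fetal list as small as the real 5.7e-06 came from 2 of the 10 splits, the smallest of the others being 8.0e-12. That split set both libraries of number 1 and GFP-high 4 against both libraries of number 3 and GFP-negative 4. It keeps the GFP-high and GFP-negative libraries of number 4 apart, the pair with the largest shift of the list (median 0.55), so whether that pair or the replicate number lies behind it stays open. With the block the fetal list had an adjusted p of 3.2e-07, and the smallest over the other splits that part every pair, computed after these values were seen, was 3.4e-07. The blocked call was also lost with an estimated correlation (adjusted p = 0.54) and with fry (adjusted p = 0.29). Without the block the fetal list also passed in other mixed splits, with camera adjusted p of 0.00078, 4.4e-05 and 7.3e-05. The split that gave 4.4e-05 kept both libraries of number 4 on the same side. With the preset correlation, lists thus passed in splits that mix GFP-high and GFP-negative libraries.

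A run of neighbouring genes on chromosome 9 stood higher in GFP-high cells. It spans 12 genes with mean CPM of at least 5, from Pomgnt2 to Cdcp1 (121981606 to 123216038 in GRCm38), among them the kinesin gene Kif15, Zdhhc3 and Exosc7, with a median blocked log2 fold change of 0.67 and a range of 0.46 to 0.87. Of the 12 genes 11 were higher in all 3 pairs, 4 passed the threshold with the block and 0 without it, and the pair medians were 0.47, 0.81 and 0.72. A GC content trend was argued against, since the median stayed at 0.666 with the trend removed. Chance placement of changed genes remains open by the limit set beforehand: the highest mean statistic of 9 neighbouring genes was 4.26, above the 95th percentile of 3.54 over 1000 shuffles of gene positions and under their maximum of 4.73, and 2 shuffles reached it. The scan also held a window on chromosome 3, from Chtop to Sprr2a3, with a mean statistic of 3.89. That lies above the 95th percentile too, and 10 shuffles reached it. For the run on chromosome 9, a candidate explanation is a copy number difference of its segment between the sorted fractions, though a ratio does not say which fraction changed. The fold changes of the 12 genes had a weighted mean of 1.58 and varied no more than their errors across genes (heterogeneity chi-square p = 0.944). The flanking genes had medians of 0.01 (10 genes before) and -0.06 (8 genes up to the chromosome end). A copy number difference cannot be told apart from coordinated regulation, because the 12 genes were picked for being high. The 3 low-expressed genes inside the interval, which were not, had a median of 0.08. Their SEs of 0.40, 1.21 and 0.53 are too wide to tell 0 from 0.67, so they do not decide the question.

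A set of 18 immediate-early genes, which cells induce within minutes of stimulation, was picked from the fixed lists after the values were seen, so it does not test whether such genes fell as a group. Of the 18 genes 15 had a negative log2 fold change, with a median of -0.28; 0 passed without the block and 4 fell with it, among them Egr1 (log2 fold change -0.48), Egr2 (-0.85) and Nr4a1 (-0.64). The pair medians were -0.39, -0.39 and -0.04, so pair 4 hardly showed it. For the 11 heat shock and chaperone genes alone, picked afterwards, a lower response in GFP-high cells was argued against. Their median was 0.107 and none was negative. The whole heat shock and dissociation list fixed beforehand had 13 of 21 members above 0 and a median of 0.07. Its direction was down (camera adjusted p = 0.26), with 0 members higher and 3 lower past the threshold in the blocked fit. It therefore does not settle the question beyond the 11 genes. The pair medians of the 11 genes were 0.18, 0.06 and 0.11, so a small difference in the other direction was not excluded. Lower EGFR and RAS/MAPK output stays open: 14 feedback genes, picked afterwards, had a median of -0.114 with 9 negative and pair medians of -0.12, -0.16 and -0.15. The whole list fixed beforehand had 16 of 29 members above 0, a median of 0.06 and a camera adjusted p of 0.73, with 0 members higher and 2 lower past the threshold in the blocked fit. A difference in time or handling between the sorts that acts on immediate-early genes alone also stays open and was not tested.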
